A study of Mus musculus with 4 samples.

How the data were processed

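The deposited matrices give expected counts per gene and cell barcode: as deposited, the values are UMI counts from which background had already been subtracted before upload, by a tool not given in the sources used here. From 1.85% to 2.99% of the stored values are whole numbers, and at least 13.2% to 15.2% of the molecules of a library had been removed. Per the submitters' processing notes Cell Ranger 7.0.0 and the mm10 build were used; their roles are not given. The labels describe 10x 3' v3 libraries from B6C3 mice. The test plan had assumed raw counts. Since the values are estimates, sums per library and cell class were rounded to whole counts before the count models were fitted. The deposited barcodes numbered 14392 and 16002 in WT and 15941 and 31844 in rd1. Each file holds 32285 gene symbols, of which 31372 (97.2%) matched a GRCm38 gene of GENCODE vM21 once by symbol.

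The tests, gene lists, marker sets, naming rule and most alternatives were fixed before the data were examined. Cells needed at least 1000 UMIs, 500 detected genes and at most 20% mitochondrial UMIs. Clusters were built on all cells with at least 500 UMIs and 250 genes: values were scaled per cell and log transformed, 2000 variable genes gave 40 principal components, and cells with 20 nearest neighbours were joined where they shared at least 3. Leiden clustering in igraph 0.11.9 at resolution 1 gave 53 clusters, and resolution 0.5 gave 40. A cluster took the class with the highest mean marker excess over the median cluster, where at least 3 markers had log2 of at least 1 and were detected in at least 5% of its cells (8 for rod bipolar, 4 for red blood cells). It stayed without a name where another class came within 0.5 log2 with 80% of its markers raised. A cluster with more markers of another class than of its own among its 10 leading genes was set aside from its class. These thresholds and the set-aside step were chosen after seeing the clusters, before any gene was tested.

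The plan named Scrublet for doublets, but it marked 0.1%, 0%, 0% and 11.6% of cells against 11.5%, 12.8%, 12.8% and 25.5% expected from loading. A score of the same kind replaced it: sums of 2 random cells of different classes were added in the expected number, and a cell was marked where the sums among its 30 nearest neighbours exceeded 0.5 of the observed cells. A first version of that score removed nearly all WT cells other than rods and was recalibrated. The score removed 86, 78, 265 and 1498 cells (0.896%, 0.788%, 2.26% and 5.96%), well under the expected rates, so doublets remain.

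Genotypes were compared on sums per library and class with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F test), with Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change over the square root of F. A class was tested where each library held at least 30 of its cells, which left 8 classes. Class shares were tested with the same tool on cell counts, with all kept cells of the library as offset. Differences of the genotype effect between rods and another class came from the genotype by class term with library as a block. An exact permutation test of 2 against 2 cannot fall under p = 0.333. The 30 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted within a class, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. A list describes genes by their known roles and was not chosen on these samples.

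Named genes are Pde6b in each class, and per class the called genes with the largest log2 difference of at least 1, non-overlapping genotypes and a mean of at least 20 CPM in the higher genotype. The rule took 8 per direction in rods and Müller glia and 4 elsewhere. It passed over predicted genes, clone names, mitochondrial, ribosomal and sex-linked genes, and genes held by all other cells at over 5 times the level of the class. To these came the 3 members with the smallest p that moved in the direction of each called list, and 2 members of 5 lists on AP-1, JNK, apoptosis, calpain and gliosis in rods and Müller glia. Atf3, Ier2, Jun, Fos, Mapk8, Mapk9, Mapk10, Gnat1, the cone genes Opn1sw, Opn1mw and Arr3, Nrl in rods, and markers of other cells were named outside the rule, after seeing the data. Where a genotype had 0 counts, a bound is given that sets 3 counts in it. Where it had 1 to 3 counts, the ratio has an exact 95% interval that covers counting error only. No fitted fold is given for those genes. Some genes that the rule takes are not reported here.

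Alternatives were the replicate number as a block, DESeq2 1.42.0, RLE size factors, no expression filter, each library left out in turn, at most 10% mitochondrial UMIs, at least 2000 UMIs, doublets kept, resolution 0.5, and testing without genes held mostly by other cells. Shares were also tested with TMM over classes and without rods in the denominator, where only cells named rods were left out and set-aside and unnamed clusters stayed. Chosen after seeing the data were at least 500 UMIs per cell, set-aside clusters returned to their class, and unnamed clusters left out of the denominator. Microglia were not run at 10% mitochondrial UMIs or 2000 UMIs, with under 30 cells in a library. In simulated tests on the same designs 200 genes per class were given folds of 1.5, 2 and 4. The recovered share of 4-fold changes ran from 31.8% in microglia to 77.3% in rods and rod bipolar cells; of 2-fold changes it was 23.9% in rods and 1.49% in microglia. False calls made up 1.64% to 10% of the calls. The simulated counts gave genes of like level the same spread. They held no replicate effect, no RNA of other cells and no difference in cell quality. These shares therefore need not hold for the real counts.

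Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, matplotlib 3.10.9 and R 4.3.3. Sequence reads were not used here, so the Pde6b lesion itself was not tested. Classes with under 30 cells in a library, such as horizontal cells, ganglion cells, astrocytes and mural cells, have shares but no gene test.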

Results

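Retinas of wild-type (WT) mice and of rd1 mice, a line with a defective gene for the beta subunit of rod phosphodiesterase (Pde6b), were profiled at postnatal day 15 by single-cell RNA sequencing from the 3' end of transcripts. The deposited matrices hold 4 libraries, 2 per genotype. Sequenced molecules (UMIs) came to 3.38e+07 and 3.67e+07 in the WT libraries and 5.60e+07 and 7.48e+07 in the rd1 libraries, in replicate order. After the cell filters 9517 and 9825 WT cells and 11455 and 23624 rd1 cells remained, with a median of 1908, 1866, 3791 and 2265 UMIs per cell. The labels do not say whether the libraries come from separate animals, so each p-value measures only the spread between these 4 samples. The libraries hold no JNK inhibitor treatment, and its effect was not analysed here. Errors after ± are standard errors with n = 2 libraries per genotype, and log2 differences are rd1 minus WT.

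Rod photoreceptors made up most cells of the WT retinas and a small part of the rd1 retinas. Their share was 69.5% (95% interval 68.6 to 70.5%) and 79.4% (78.6 to 80.2%) in WT, against 17.1% (16.5 to 17.8%) and 2.24% (2.05 to 2.43%) in rd1. The class of microglia or macrophages, immune cells that its markers did not tell apart, is called microglia here. It held 0.315% and 0.346% of WT cells and 1.99% and 3.26% of rd1 cells. The shares of amacrine cells, rod bipolar cells, horizontal cells and cones also rose. The test of shares in edgeR gave log2 differences of 2.99 ± 0.35 for microglia (adjusted p = 5.95e-08), 2.41 ± 0.64 for amacrine cells (adjusted p = 0.00359) and 1.70 ± 0.44 for rod bipolar cells (adjusted p = 0.00359). Horizontal cells gave 2.86 ± 1.03 (adjusted p = 0.0314), on 11 and 3 WT cells, and cones 0.90 ± 0.35 (adjusted p = 0.0437). Cones lost the call without any 1 library (adjusted p from 0.126 to 0.231), at most 10% mitochondrial UMIs (0.0569), at least 2000 UMIs (0.456), resolution 0.5 (0.0749) and set-aside clusters returned (0.0702), and horizontal cells without rd1 replicate 1 (0.0832) or 2 (0.0572) and with the replicate block (0.0773). Amacrine and rod bipolar cells lost it without WT replicate 2 (0.119 each), and rod bipolar cells at 2000 UMIs (0.0790).

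The rod share itself gave −2.94 ± 1.58 (adjusted p = 0.106) and did not pass; the rd1 libraries lay far apart. In rd1 replicate 2 a further 13.2% of kept cells formed a rod-like cluster with strong glial transcripts that was set aside, and 14.6% formed a cluster given no name. With set-aside clusters returned to their class, a setting chosen after seeing the data, the rod shares were 69.6%, 79.5%, 17.9% and 15.4%, and the difference was −2.16 ± 0.33 (adjusted p = 7.41e-06). Shares within a library sum to 100%, so fewer rods raise every other share. With the cells named rods left out of the denominator 0 classes passed, as was the case with TMM scaling over classes. The set-aside rod-like cluster and the cluster given no name stayed in that denominator, which lowers the other shares in rd1 replicate 2. The 5 classes that passed became 2 without WT replicate 2 and 3 without rd1 replicate 2.

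**Figure D1:**
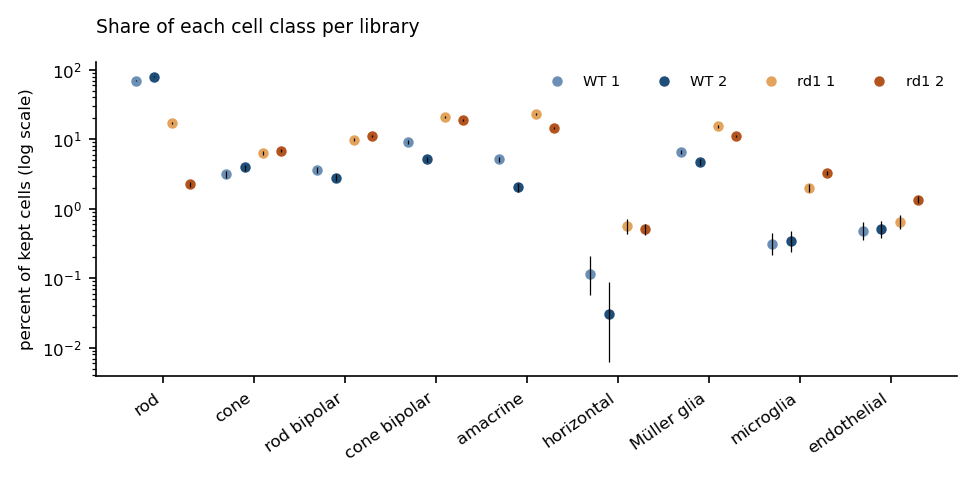
Share of each cell class among the kept cells of the 4 libraries, on a logarithmic axis. Bars are exact binomial 95% intervals.

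Rods of the rd1 retina had lost most of the Pde6b transcript and part of the light-detection programme. Pde6b fell from 2261 and 1894 CPM (counts scaled to equal library sums) in WT rods to 329 and 282 in rd1 rods (log2 −2.88 ± 0.29, adjusted p = 7.36e-04). The guanylate cyclase activating proteins, which restore cGMP after light, fell as well: Guca1a by log2 −3.26 ± 0.28 (adjusted p = 2.38e-04) and Guca1b by −2.16 ± 0.29 (adjusted p = 0.00295). The rod transcription factor Nrl gave −0.86 ± 0.29 (adjusted p = 0.150). All 26 measured members of the rod phototransduction list were lower in rd1; 2 fell among all genes and 6 when adjusted over the list alone. The retinal guanylate cyclase gene Gucy2f gave −0.83 ± 0.21 (adjusted p = 0.0540). The list fell in camera at a preset correlation of 0.01 (adjusted p = 2.64e-10), with adjusted p = 0.657 with an estimated correlation.

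By the naming rule the other large falls in rods were Slc24a5, a cation exchanger (−2.87 ± 0.29, adjusted p = 7.87e-04), Klhl3, a ubiquitin ligase adaptor (−2.73 ± 0.31, adjusted p = 0.00125), the kinase gene Stk35 (−2.60 ± 0.33, adjusted p = 0.00221), Pdzph1 (−2.45 ± 0.23, adjusted p = 4.71e-04), the axonemal dynein Dnah9 (−2.36 ± 0.28, adjusted p = 0.00170) and the transcript Ube4bos1 (−3.07 ± 0.58, adjusted p = 0.0267). Glycolysis, the main energy route of photoreceptors, had 18 of 20 members lower: enolase Eno1 fell by log2 −1.57 ± 0.26 (adjusted p = 0.0101), and the phosphofructokinases Pfkl and Pfkp by −1.20 ± 0.21 (adjusted p = 0.0129) and −1.21 ± 0.25 (adjusted p = 0.0254). In that list 4 members fell among all genes and 7 over the list alone (camera adjusted p = 3.59e-06; adjusted p = 0.757 with an estimated correlation). Of 19 ribbon synapse members 15 were lower and 2 passed, the calcium channel Cacna1f (−0.90 ± 0.22, adjusted p = 0.0466) and the release-site protein Rims2 (−1.04 ± 0.25, adjusted p = 0.0490), with list adjusted p = 0.00484, or 0.624 with an estimated correlation. Cacna1f and Rims2 no longer passed without any 1 library, Eno1, Pfkl and Pfkp without either rd1 library, and Ube4bos1 without WT replicate 2. With set-aside clusters returned, Eno1 (−1.07, adjusted p = 0.130) and Pfkp (−0.86, adjusted p = 0.202) did not pass either.

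Immediate early genes and transcription factors of the stress response rose in rd1 rods. Junb, a component of the AP-1 transcription factor that JNK signalling acts on, rose from 10.2 and 15.5 CPM to 301 and 185 (4.08 ± 0.32, adjusted p = 1.73e-04). The nuclear receptor Nr4a1 rose by 3.74 ± 0.25 (adjusted p = 6.90e-05), the stress factor Atf3 by 2.49 ± 0.34 (adjusted p = 0.00355) and Ier2 by 1.87 ± 0.25 (adjusted p = 0.00326). Dusp1, a phosphatase that switches off MAP kinases, was 930-fold higher (95% interval 164 to 37034) on 1 WT count, with a level 5.38 times higher in the other cells. The AP-1 factors Jun (0.16 ± 0.36, adjusted p = 0.888) and Fos (1.92 ± 0.90, adjusted p = 0.411) did not pass. Of 15 members of this list 14 were higher and 5 rose among all genes (camera adjusted p = 6.38e-08; adjusted p = 0.624 with an estimated correlation; adjusted p = 0.0147 with fry). The leucine zipper factors Cebpb and Cebpd rose by 8.01 ± 0.50 (adjusted p = 5.85e-05) and 7.75 ± 0.54 (adjusted p = 2.38e-04).

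The JNK cascade list as a whole did not pass in rods (25 members, 11 higher, camera adjusted p = 0.351). Within it Map3k5, the kinase ASK1 upstream of JNK, rose by 3.90 ± 0.71 (adjusted p = 0.0141), and Gadd45b, another member of the list, by 3.42 ± 0.28 (adjusted p = 1.91e-04). Mapk10, which encodes JNK3 and is named here for the topic of the series, rose by 3.49 ± 0.70 (adjusted p = 0.0227) to 10.8 and 5.08 CPM, with a level 9.29 times higher in the other cells. Mapk8 (−0.13 ± 0.26, adjusted p = 0.875) and Mapk9 (−0.27 ± 0.28, adjusted p = 0.735), which encode JNK1 and JNK2, did not pass. Map3k5 lost its call without WT replicate 2.

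Cell-death genes moved in part. The p53 target Bbc3 (PUMA) was 84.3-fold higher (95% interval 26.5 to 429) on 3 WT counts, and p53 itself (Trp53) gave 1.33 ± 0.35 (adjusted p = 0.0685). The apoptosis list had 10 of 14 members higher, 2 of them called (camera adjusted p = 0.00979; adjusted p = 0.624 with an estimated correlation; adjusted p = 0.0253 with fry). The list of calpains, PARP and cGMP-dependent kinase did not pass (9 members, camera adjusted p = 0.112). In it the calpain small subunit Capns1 rose by 2.17 ± 0.45 (adjusted p = 0.0326), and the cGMP-dependent kinase Prkg1 gave 2.74 ± 0.84 (adjusted p = 0.114). Bbc3 did not pass without WT replicate 2, nor Capns1 without either rd1 library or with set-aside clusters returned.

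Protein-folding and oxidative stress genes rose alongside. Among 22 members of the unfolded protein response and ATF4 list 14 were higher and 5 rose, such as asparagine synthetase Asns (2.99 ± 0.34, adjusted p = 0.00125) and Sesn2 (2.50 ± 0.38, adjusted p = 0.00612). Chac1, a glutathione-degrading ATF4 target, was 365-fold higher (95% interval 62.5 to 14694) on 1 WT count. The list passed in camera (adjusted p = 0.00330), with adjusted p = 0.757 with an estimated correlation. The chaperone Hsph1 rose by 1.59 ± 0.22 (adjusted p = 0.00373) and Hsp90ab1 by 1.46 ± 0.27 (adjusted p = 0.0149), and Hspb1 was 127-fold higher (95% interval 19.8 to 5287) on 1 WT count. Heat shock proteins had 12 of 13 members higher and 4 called (camera adjusted p = 4.61e-05; adjusted p = 0.757 with an estimated correlation). In the NRF2 and antioxidant list 15 of 18 were higher and 3 rose, the autophagy receptor Sqstm1 (2.07 ± 0.35, adjusted p = 0.0108), sulfiredoxin Srxn1 (1.29 ± 0.23, adjusted p = 0.0137) and metallothionein Mt2 (5.64 ± 0.87, adjusted p = 0.0125), Mt2 with a level 13.3 times higher in the other cells. That list had camera adjusted p = 3.42e-04, and adjusted p = 0.757 with an estimated correlation. Without WT replicate 2 Hspb1, Mt2 and Srxn1 did not pass; Hspb1 was also lost without WT replicate 1, Srxn1 without rd1 replicate 1, and Hsp90ab1 without rd1 replicate 2.

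A growth factor, structural proteins and genes of the gliosis list rose in rd1 rods too. The neuroprotective growth factor Fgf2 rose from 16.8 and 18.6 to 172 and 242 CPM (3.43 ± 0.30, adjusted p = 2.43e-04), and the collagen-processing protein Pcolce by 7.59 ± 0.49 (adjusted p = 5.85e-05). The nuclear lamina gene Lmna, the actin-binding Tagln2 and the annexin Anxa2 had 0 counts in WT rods and were at least 566-, 613- and 365-fold higher. All 8 measured reactive gliosis members were higher and 5 rose (camera adjusted p = 2.73e-07; adjusted p = 0.624 with an estimated correlation). All 5 interferon and MHC class I members were higher and 1 rose, the interferon signalling factor Irf9 (1.96 ± 0.45, adjusted p = 0.0387; list adjusted p = 0.0163, or 0.624 with an estimated correlation). Irf7 (0.56 ± 0.36, adjusted p = 0.508) and H2-D1 (3.26 ± 1.26, adjusted p = 0.250) did not pass. Irf9 was lost without any 1 of 3 libraries, the exception being WT replicate 1, and with DESeq2. The haemoglobin genes Hba-a1 (21895-fold, 95% interval 3927 to 8.65e+05) and Hbb-bt (4830-fold, 864 to 1.91e+05) were also higher, each on 1 WT count, and neither passed without either WT library.

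In edgeR 557 of 11696 genes tested in rods changed, 412 up and 145 down, and the count was 302 without WT replicate 2 and 296 with rods of at least 2000 UMIs. It rose to 1777 with the replicate block (990 up, 787 down), 1244 with no expression filter (745 up, 499 down) and 883 at 500 UMIs, a limit chosen after seeing the data, so the excess of rises shrank under the first 2 of these. At 2000 UMIs Map3k5, Capns1, Sqstm1, Srxn1, Irf9, Rims2 and Hba-a1 did not pass, and with set-aside clusters returned or at resolution 0.5 Ube4bos1, Hsp90ab1, Capns1, Irf9, Rims2, Eno1 and Pfkp did not. Of the 412, 178 are held mostly by other cells, at over 5 times the rod level, 44 had at most 3 counts in WT rods, and 209 were neither. Markers of other cells were higher in rd1 replicate 2: the Müller glia gene Glul stood at 46.3 and 33.01 CPM in WT rods and 25.0 and 370 in rd1 rods, Apoe at 54.3, 41.8, 12.4 and 331. The median mitochondrial share of UMIs per rod was 0.110% and 0.0238% in WT against 0.582% and 1.24% in rd1, a difference in cell state or quality that went with the genotype and was not tested apart from it. Rods of the genotypes fell into separate clusters: 1 cluster held 86.8% and 71.7% of WT rods but 9.67% and 3.03% of rd1 rods, another held 1.42% and 0.295% against 87.1% and 90.9%. The deposited values had background subtracted, which leaves exact zeros, so the bounds given for genes with 0 counts depend on that step. Of all tested genes 43.4% had non-overlapping genotypes, against 33.3% by chance.

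**Figure D2:**
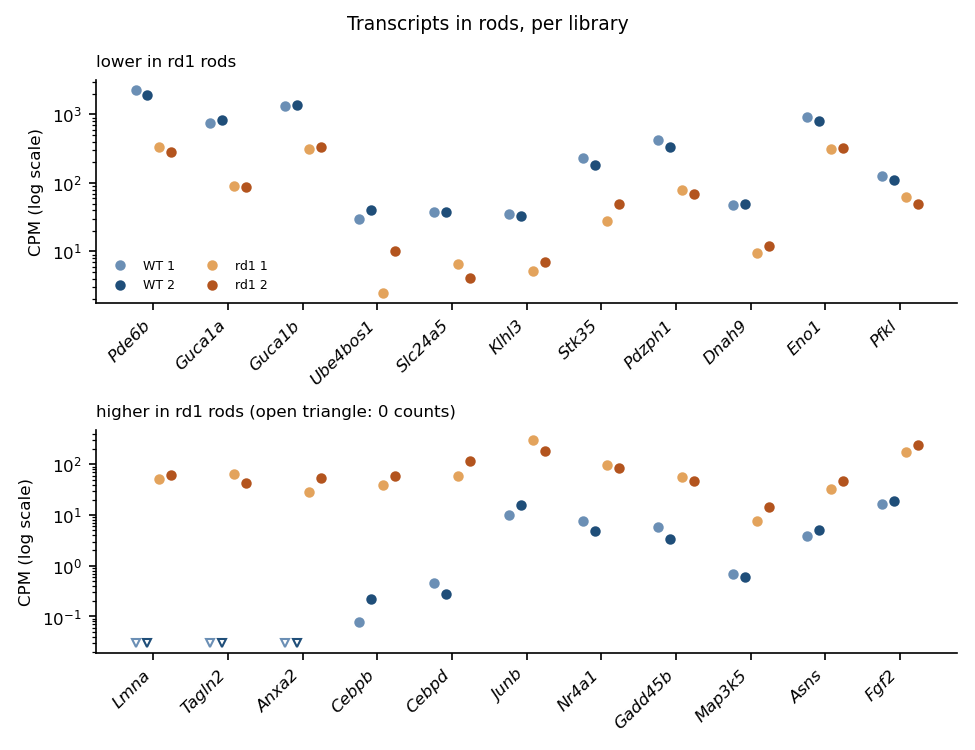
Levels of named genes in the rods of each library. Each point is the sum over the rods of 1 library in CPM, on a logarithmic axis.

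Cones kept their own opsins but showed part of the rod response. Opn1sw (0.24 ± 0.31, adjusted p = 0.936), Opn1mw (−0.03 ± 0.33, adjusted p = 0.994) and cone arrestin Arr3 (1.17 ± 0.30, adjusted p = 0.182) did not pass. Junb (2.84 ± 0.32, adjusted p = 0.0181), Ier2 (2.77 ± 0.32, adjusted p = 0.0181) and Fgf2 (1.83 ± 0.29, adjusted p = 0.0365) rose. The early growth response factor Egr3 was 130-fold higher (95% interval 23.1 to 5170) on 1 WT count and the retinoic acid enzyme Aldh1a1 72.1-fold (19.7 to 600) on 2. The lipid-binding protein Dbi, the metallothioneins Mt1 and Mt2, the filament protein Vim and S100a6 had 0 counts in WT cones and were at least 760-, 273-, 114-, 63.6- and 45.1-fold higher. Some Müller glia markers moved the same way in the cones of WT and rd1: Glul stood at 0 and 0 against 20.8 and 335 CPM and Rlbp1 at 0 and 0 against 20.5 and 164. Apoe, at a higher level than either in Müller glia, hardly moved in cones (0 and 0 against 0 and 4.20). Pfkl (−1.63 ± 0.26, adjusted p = 0.0401), Gpsm2 (−3.67 ± 0.55, adjusted p = 0.0407) and Ankrd37, a hypoxia target (−3.10 ± 0.39, adjusted p = 0.0191), fell.

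Rod genes fell in cones as well: Pde6b by log2 −4.36 ± 0.34 (adjusted p = 0.00321), the exchanger Slc24a1 by −2.48 ± 0.34 (adjusted p = 0.0287), Gucy2f by −2.36 ± 0.29 (adjusted p = 0.0191) and Guca1b by −2.13 ± 0.31 (adjusted p = 0.0326), while Nrl gave −2.03 ± 0.35 (adjusted p = 0.0520). Beside these, cones of WT carried rod RNA: Gnat1, the rod transducin, stood at 1815 and 2967 CPM in WT cones and 565 and 396 in rd1 cones (−2.33 ± 0.36, adjusted p = 0.0365). In cones 9 lists passed in camera, among them AP-1 (12 of 14 higher, 3 called, adjusted p = 1.94e-09) and rod phototransduction (24 of 26 lower, 5 called, adjusted p = 1.53e-17); with an estimated correlation their adjusted p ran from 0.435 to 0.710. In edgeR 50 of 10599 genes changed in cones, 32 up and 18 down; 21 of the 32 had at most 3 WT counts and 9 are held mostly by other cells. The count was 6 without WT replicate 2, when each cone gene taken by the naming rule lost its call except Pde6b, Dbi, Egr3 and Mt1, and 580 and 228 without rd1 replicate 1 or 2. S100a6, Gpsm2, Fgf2 and Vim were also lost without WT replicate 1, and Ankrd37, Fgf2 and Vim with predicted doublets kept.

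The genotype effect differed between rods and cones for 292 genes, 202 of them with the larger value in rods. Guca1a fell in rods and stood at 0.36 (adjusted p = 0.864) in cones (difference −3.57 ± 0.21, adjusted p = 7.35e-08), and Asns (2.59 ± 0.29, adjusted p = 1.03e-04), Gadd45b (2.57 ± 0.43, adjusted p = 0.00574) and Map3k5 (3.35 ± 0.80, adjusted p = 0.0337) had larger values in rods. Against Müller glia 277 genes differed. Junb rose more in rods (4.07 ± 0.61, adjusted p = 0.0196), with −0.03 in Müller glia, and Fgf2 differed by 2.34. The count against Müller glia was 1143 without rd1 replicate 1, 416 without WT replicate 1 and 445 without WT replicate 2.

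Müller glia, the support cells that span the retina, carried more transcripts of gliosis and of the interferon response in rd1. The filament protein Gfap, the standard marker of gliosis, rose from 3.58 and 3.81 to 210 and 144 CPM (5.59 ± 0.31, adjusted p = 0.00325). The protease inhibitor A2m rose by 5.29 ± 0.37 (adjusted p = 0.00939), and Serpina3n, another, was 49.4-fold higher (95% interval 16.8 to 240) on 3 WT counts. Of 18 reactive gliosis members 15 were higher, with 5 up among all genes and 13 over the list alone (camera adjusted p = 2.45e-13; adjusted p = 0.406 with an estimated correlation). All 24 interferon and MHC class I members were higher, 3 called and 20 over the list alone: the antiviral proteins Bst2 (3.65 ± 0.33, adjusted p = 0.0198) and Ifitm3 (2.89 ± 0.23, adjusted p = 0.0162) and the MHC subunit B2m (2.38 ± 0.24, adjusted p = 0.0224). That list gave camera adjusted p = 4.66e-21, and adjusted p = 0.447 with an estimated correlation. The complement regulator Serping1 rose (2.44 ± 0.24, adjusted p = 0.0217), in a list with 5 of 6 members higher (adjusted p = 0.00120, or 0.447 with an estimated correlation). Cone transcripts were higher beside these in rd1 Müller glia, though none of them passed: Gnb3 was 60.2-fold higher (95% interval 10.7 to 2392) on 1 WT count (adjusted p = 0.142), Gngt2 40.3-fold (11.03 to 334) on 2 (adjusted p = 0.0964), and Arr3, with 0, at least 10.5-fold (adjusted p = 0.113). A cluster with Müller glia and cone markers that was removed as doublets held 4 and 1 WT cells and 24 and 412 rd1 cells.

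Müller glia also raised Mt2 (4.15 ± 0.51, adjusted p = 0.0478), haem oxygenase Hmox1 (3.86 ± 0.46, adjusted p = 0.0427), the protease inhibitor Cst3 (3.30 ± 0.40, adjusted p = 0.0457) and Ndrg1 (3.23 ± 0.30, adjusted p = 0.0198). The deubiquitinase Otud1 fell (−2.00 ± 0.24, adjusted p = 0.0427). Pde6b gave −1.54 ± 1.10 (adjusted p = 0.769). In edgeR 19 of 12610 genes changed, 18 up and 1 down. Without WT replicate 2 only 1 gene passed, Gfap, and every other Müller glia gene named here lost its call; Cst3, Hmox1 and B2m also lost it without WT replicate 1. With predicted doublets kept the count was 4 and of the genes named here Gfap, A2m and Ifitm3 kept their calls; it was 410 with the replicate block, 566 without rd1 replicate 1 and 382 without rd1 replicate 2.

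Microglia of the rd1 retina carried more transcripts of the activated state. The class can also hold macrophages, and whether its makeup differed between the genotypes was not tested. Osteopontin (Spp1) had 0 counts in WT and was at least 130-fold higher, and cystatin F (Cst7) was 33.2-fold higher (95% interval 11.3 to 161) on 3 WT counts. The lysosomal proteases Ctsd (2.65 ± 0.28, adjusted p = 0.0128) and Ctsb (2.54 ± 0.31, adjusted p = 0.0215) and the fatty acid binding protein Fabp5 (6.07 ± 0.74, adjusted p = 0.0215) rose. Of 20 activation genes 19 were higher, 6 called and 14 over the list alone (camera adjusted p = 2.41e-14; adjusted p = 0.591 with an estimated correlation). Among 15 homeostatic genes 11 were lower, 0 called by edgeR and 6 over the list alone (adjusted p = 9.36e-06, or 0.651 with an estimated correlation): Tmem119 gave −1.82 ± 0.34 (adjusted p = 0.0752), P2ry13 −1.61 ± 0.35 (adjusted p = 0.123) and Selplg −1.85 ± 0.32 (adjusted p = 0.0568). All 18 AP-1 and immediate early genes were lower in rd1 microglia, 9 over the list alone (adjusted p = 1.87e-11, or 0.595 with an estimated correlation), such as Jun (−1.82 ± 0.36, adjusted p = 0.0917). Microglia also differed in measures of quality: the median mitochondrial share of UMIs was 2.06% and 0.878% in WT against 2.83% and 2.97% in rd1, and the median UMIs per cell 3894 and 3311 against 2886 and 1681.

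In edgeR 26 of 6473 genes changed in microglia, 20 up and 6 down, on 30 and 34 WT cells and 228 and 770 rd1 cells. The B-lymphocyte genes Igkc, Cd79a and Ly6d, at least 212-, 86.4- and 82.4-fold lower, came from 1 cell of each WT library. Il7r, a cytokine receptor, fell by log2 −3.81 ± 0.53 (adjusted p = 0.0285). Trpm1, a bipolar cell channel, was at least 13.2-fold higher, and the neuronal transcript Mir124-2hg 51.6-fold (95% interval 9.23 to 2042) on 1 WT count; the other cells held Trpm1 at 5.24 and Mir124-2hg at 4.07 times the microglial level. The count was 4 without WT replicate 1, when Ctsd, Ctsb, Il7r, Trpm1 and Mir124-2hg lost their calls, 17 without WT replicate 2, when Ctsb and Mir124-2hg lost theirs, and 176 and 121 without rd1 replicate 1 or 2, when Cd79a, Ly6d and Il7r lost theirs.

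**Figure D3:**
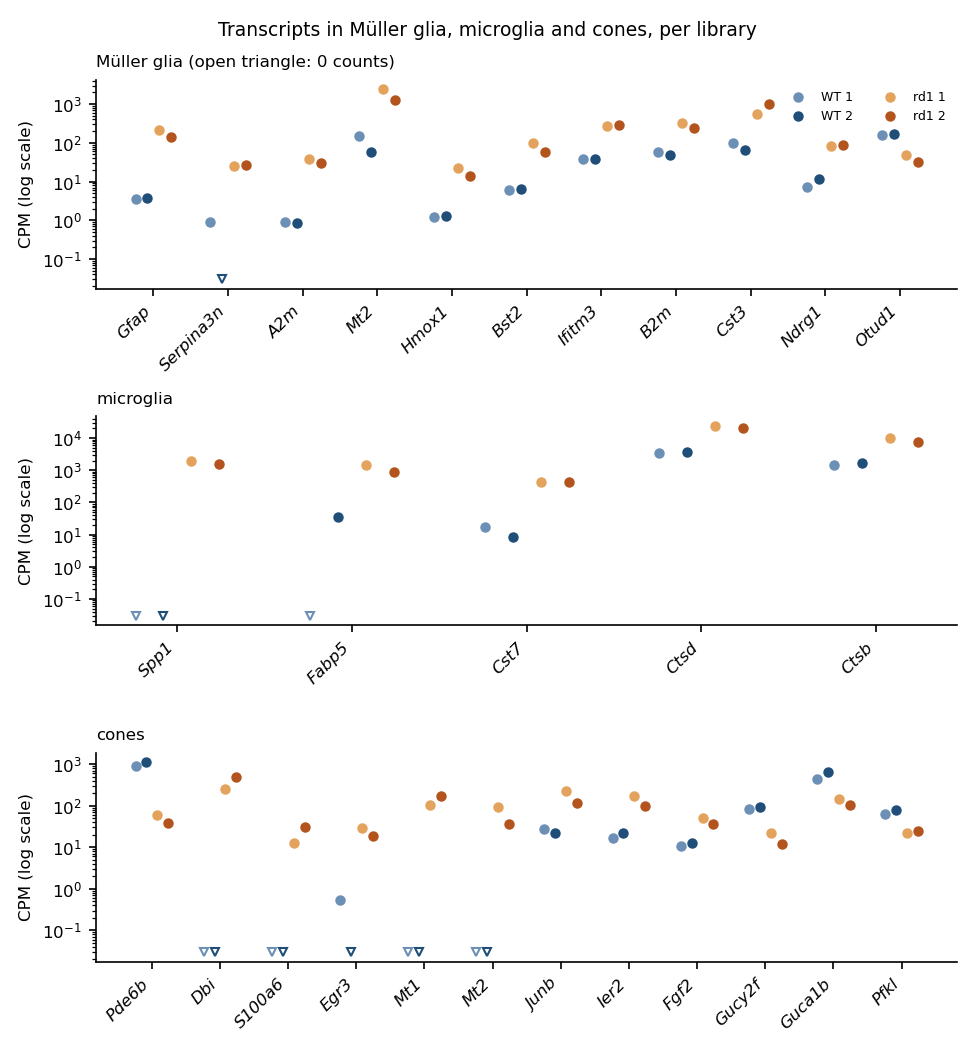
Levels of named genes in Müller glia, microglia and cones of each library, in CPM on a logarithmic axis.

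In bipolar and amacrine cells, which lie downstream of the photoreceptors, 0 genes passed in the planned edgeR comparison, and the count depended on the setting. Rod bipolar cells had 0 of 10490 genes called (485 at an unadjusted p under 0.05; 27 with DESeq2), cone bipolar cells 0 of 12894 (239 unadjusted; 5 with DESeq2) and amacrine cells 0 of 13694 (502 unadjusted; 24 with DESeq2). Glycolysis was lower in rod bipolar cells (17 of 20 members, camera adjusted p = 3.57e-12; adjusted p = 0.999 with an estimated correlation) and in cone bipolar cells (18 of 20, adjusted p = 9.26e-08; adjusted p = 0.918 with an estimated correlation), with Pfkl at −1.06 ± 0.28 (adjusted p = 0.534) and −0.69 ± 0.23 (adjusted p = 1.00). In simulated counts, which are simpler than the real ones, 4-fold changes were recovered at 77.3% in rod bipolar, 62.1% in cone bipolar and 65.2% in amacrine cells. Simulated 2-fold changes were recovered at 11.9%, 14.9% and 17.9%, so smaller changes would mostly be missed. With the replicate block the counts were 249, 9 and 12, with no expression filter 127, 138 and 161, without rd1 replicate 1 294, 122 and 211, and without rd1 replicate 2 133, 101 and 90. Without WT replicate 1 or 2 cone bipolar cells had 30 and 3 and amacrine cells 60 and 9; without genes held mostly by other cells amacrine cells had 1. Endothelial cells had 1 of 7599 genes called, the haemoglobin gene Hbb-bs (0 WT counts, at least 1034-fold higher), with 207 without rd1 replicate 1, 22 without rd1 replicate 2, 3 without WT replicate 1 and 0 without WT replicate 2.

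**Figure D4:**
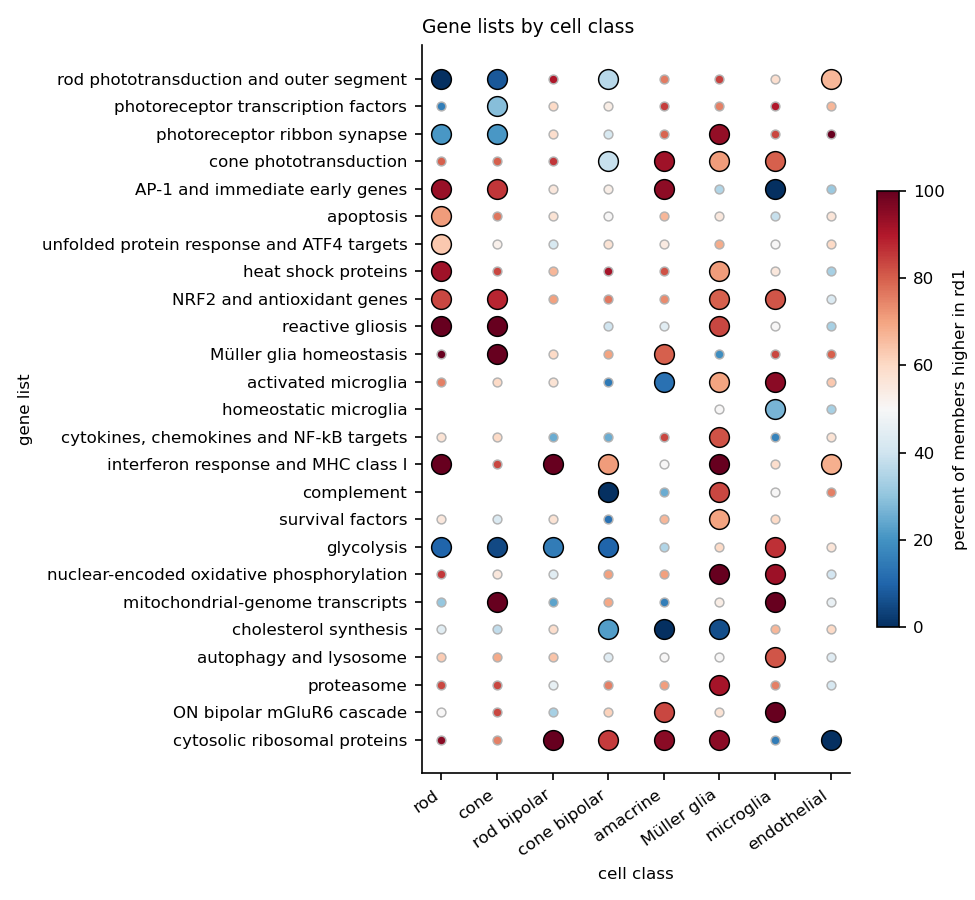
Percent of measured members of each gene list that were higher in rd1, by cell class. Large dots with a black edge had an adjusted p under 0.05 in camera at the preset correlation.

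Summed over all kept cells of a library, 1248 genes changed, 302 up and 946 down. Pde6b fell by log2 −5.55 ± 0.37 (adjusted p = 0.0124), beyond its value within rods, and Spp1 rose by 7.54 ± 0.45 (adjusted p = 0.0110). The excess of falls turned into an excess of rises without WT replicate 1 (2126 rose and 1868 fell) and shrank in other settings, with 1038 and 1122 without rd1 replicate 2, 3388 and 3672 with the replicate block, and 1480 and 1725 with DESeq2. Whole libraries mix differences in cell makeup with those inside each class.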

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

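Of the tests below, the one on free RNA in rod bipolar cells was written before its result was seen; those on doublets, haemoglobin and AP-1 genes were written after. The AP-1 tests were reworded after earlier versions had been run and their genes divided by outcome, so what they exclude rests on each gene's own values; the interval rule of the doublet test was added after its value was seen.

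The 178 genes that rose in rd1 rods but are held mostly by other cells could be free RNA left after the background subtraction. Their median level in rods was 0.560% and 0.559% of that in other cells in WT, and 7.52% and 10.6% in rd1. If free RNA were the cause, such genes should also be higher in rod bipolar cells by a median log2 above 1. The median over the 17 genes also held mostly by other cells there was 0.56, with 23.5% of them non-overlapping, which left the question open. In cones the median level of these genes, as a share of that in other cells, was 0% and 0% in WT and 0.535% and 6.72% in rd1. In microglia it was 0% and 0% against 6.39% and 20.7%, and in endothelial cells 0% and 0.880% against 0% and 20.8%. In bipolar and amacrine cells and Müller glia that share was lower in both rd1 libraries than in both WT libraries. Taken over the sum of these genes, the share was lower in rd1 cones too, at 35.9% and 45.4% in WT against 24.7% and 32.3%. It was also lower in both rd1 libraries in microglia and endothelial cells. Only in rods was it higher, at 1.43% and 1.90% against 7.85% and 11.2%. Outside rods the other cells of WT were mostly rods, so these shares also move with cell makeup and do not decide. Doublets of a rod and another cell might also bring the 178 genes in. Among rods of 1000 to 2000 UMIs 122 such genes were called, 68.5% of the count in all kept rods and near the bound of 66.7% set for doublets, and with doublets kept the count was 174; of the 178 themselves 163 were still called up in the smaller rods, 95 of them still held mostly by other cells. The 95% interval of that 68.5%, from 61.2% to 75.3%, holds the bound, so the count does not decide. Few doublets were marked, so keeping them could hardly change the count. Rods under 2000 UMIs can also hold some, so doublets stay open as well.

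Haemoglobin transcripts in rd1 rods may be free RNA of red blood cells in the rd1 libraries. All 4 haemoglobin transcripts were higher in both rd1 libraries than in both WT libraries in 4 of the 8 tested classes, where at least 7 were needed to point to free RNA and under 4 to argue against it. Hbb-bs stood at 0 CPM in WT rods of both libraries and at 1081 and 4101 CPM in rd1 rods.

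AP-1 and immediate early genes respond to dissociation, so handling that differed between the genotypes might account for them. If it acted on all cells alike, rods and Müller glia should change together. Of the 5 called genes 3 had a larger effect in rods in edgeR, Junb (4.07 ± 0.61, adjusted p = 0.0196), Ier2 (2.49 ± 0.49, adjusted p = 0.0486) and Dusp1 (adjusted p = 0.00104). For Junb this argues against handling that acted on all cells alike. For Ier2 and Dusp1 free RNA, left open below, may enter the rod values, so the difference does not decide. Of the other 2, Nr4a1 (3.31, adjusted p = 0.377) and Atf3 (2.67, adjusted p = 0.595), 0 passed and handling stays open. Junb and Ier2 also rose in cones, as given above. Free RNA of other cells would leave these genes at a small share of the level there, as for 47 markers of other classes in the rd1 libraries (median 0.692% and 4.30%, highest 28.0% for Slc6a9 and 34.5% for Clu). Nr4a1 (138% and 383%) and Atf3 (120% and 217%) stood above the other cells and Junb (45.9% and 74.0%) above each of these markers, which argues against free RNA for them. Ier2 (27.3% and 64.6%) and Dusp1 (16.9% and 23.1%) did not in both libraries and stay open. Handling that affects rods, or rods and cones, but not Müller glia was not tested and stays open as well.

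Other results that stood out are given as values. The genotype effect differed between rods and cones for 292 genes and between rods and Müller glia for 277. Rod minus cone log2 differences were −3.57 for Guca1a, −2.45 for Dnah9, −1.64 for Slc24a5, −1.39 for Stk35, −1.21 for Pdzph1 and −1.08 for Eno1. They were 5.14 for Pcolce, 3.35 for Map3k5, 2.59 for Asns, 2.57 for Gadd45b, 1.72 for Nr4a1, 1.54 for Gucy2f, 1.496 for Pde6b, 1.25 for Junb, 1.09 for Hsph1 and 0.90 for Hsp90ab1, and Lmna had an adjusted p of 0.00618 in edgeR. Rod minus Müller glia differences were 6.99 for Cebpd, 4.07 for Junb, 3.11 for Map3k5, 2.34 for Fgf2, 1.69 for Hsph1, −2.33 for Guca1a and −3.15 for Klhl3, with adjusted p = 9.13e-04 for Tagln2 and 0.00104 for Dusp1 in edgeR. In rd1 replicate 2 the rod-like set-aside cluster held 13.2% of kept cells and the large cluster without a name 14.6%, against 0.786% and 0.0524% in rd1 replicate 1; their median UMIs were 1204 and 1480 and their Apoe levels 1727 and 4758 CPM.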

How the results depend on the processing

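With 2 libraries per genotype the calls depended on single libraries and on the model, and the cause of each move below was not tested. Counts were scored by size alone, as kept or moved, whichever genes they held and in whichever direction. Only the rod share could be scored as turned. On that score 137 of 249 alternative values were kept and 112 moved, and the rod share did not turn. The balance of rises and falls in whole libraries did turn without WT replicate 1, as given above. Over the named genes 2928 values were the same, 271 stronger, 130 weaker and 0 reversed. Those scored as the same include genes that neither fit called, so the total does not measure how stable the calls were. A reversal counted only where either fit called the gene. Replicate numbers are shared by the genotypes. Over genes, the difference of replicate 1 minus replicate 2 in WT was compared with the same difference in rd1. Their correlation was 0.387 in rods, 0.511 in cones, 0.493 in rod bipolar, 0.499 in cone bipolar and 0.443 in amacrine cells. It was 0.564 in Müller glia, 0.138 in microglia, 0.0748 in endothelial cells and 0.692 in whole libraries. With 2 pairs this does not show pairing, and the fit with a replicate block is an alternative.

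With the replicate block the counts of changed genes were 1777 in rods (557 without it), 321 in cones (50), 249 in rod bipolar (0), 9 in cone bipolar (0) and 12 in amacrine cells (0), 410 in Müller glia (19), 142 in microglia (26), 3 in endothelial cells (1) and 7060 in whole libraries (1248). DESeq2 gave 149 in cones, 27 in rod bipolar, 5 in cone bipolar and 24 in amacrine cells, 188 in Müller glia, 74 in microglia, 3 in endothelial cells and 3205 in whole libraries. With no expression filter the counts were 1244 in rods, 451 in cones, 127 in rod bipolar, 138 in cone bipolar and 161 in amacrine cells, 528 in Müller glia, 295 in microglia, 80 in endothelial cells, 532 for rod against cone and 841 for rod against Müller glia. At least 2000 UMIs gave 296 in rods and 54 in Müller glia, and at least 500 UMIs, chosen after seeing the data, 883 in rods. Doublets kept gave 171 in cones and 4 in Müller glia. Without genes held mostly by other cells the counts were 1 in amacrine cells, 47 in Müller glia, 2 in endothelial cells and 435 for rod against Müller glia.

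Leaving out 1 library at a time gave 302 to 520 genes in rods, 6 to 580 in cones, 0 to 294 in rod bipolar, 3 to 122 in cone bipolar and 9 to 211 in amacrine cells, 1 to 566 in Müller glia, 4 to 176 in microglia, 0 to 207 in endothelial cells, 1066 to 3994 in whole libraries and 286 to 1143 for rod against Müller glia. Named calls lost were 18 without WT replicate 1, 41 without WT replicate 2, 11 without rd1 replicate 1 and 11 without rd1 replicate 2.

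With an estimated correlation 0 lists passed in each of the 8 classes, and with fry 2 in rods and 0 in the other 7. The replicate block gave 16 lists in rods (10 without it), 5 in rod bipolar (3) and 11 in amacrine cells (7), and 5 in endothelial cells (3). Set-aside clusters returned, chosen after seeing the data, gave 18 in rods. Without genes held mostly by other cells 4 passed in cone bipolar (7) and 3 in amacrine cells, and at least 500 UMIs gave 4 in cone bipolar cells. Leaving out 1 library gave 10 to 17 lists in rods, 3 to 11 in rod bipolar, 3 to 12 in cone bipolar and 5 to 13 in amacrine cells, 9 to 18 in Müller glia (14), 10 to 17 in microglia (10) and 4 to 9 in endothelial cells.

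The 5 classes changed in share became 0 with TMM over classes, 0 without rods in the denominator and 2 to 6 with 1 library left out. The rod share difference of −2.94, which did not pass, passed at −4.47 with at least 2000 UMIs, −2.16 at resolution 0.5, −2.16 with set-aside clusters returned and −2.05 with these returned and unnamed clusters left out; with 1 library left out it ran from −5.06 to −2.12 and passed without WT replicate 1 (−3.04, adjusted p = 0.0426) and without rd1 replicate 1 (−5.06, adjusted p = 0.00650).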

Other observations

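Genes of cholesterol synthesis were lower in 3 classes of the rd1 retina. All 19 members were lower in amacrine cells, 8 over the list alone (camera adjusted p = 1.10e-16; adjusted p = 0.733 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, at −0.86 ± 0.26 (adjusted p = 0.994), Sqle, squalene epoxidase, at −0.82 ± 0.25 (adjusted p = 0.994) and Fdft1, squalene synthase, at −0.83 ± 0.22 (adjusted p = 0.912) in edgeR. In Müller glia 17 of 18 were lower (adjusted p = 5.32e-05; adjusted p = 0.406 with an estimated correlation) and in cone bipolar cells 14 of 18 (adjusted p = 0.0340; adjusted p = 0.918 with an estimated correlation). Müller glia had all 27 nuclear-encoded oxidative phosphorylation members higher (adjusted p = 6.22e-10; adjusted p = 0.622 with an estimated correlation), of which 1 was called.

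Microglia of rd1 had higher levels of all 12 mitochondrial-genome transcripts (8 over the list alone, adjusted p = 3.38e-12; adjusted p = 0.591 with an estimated correlation) and of 13 of 15 glycolysis members (adjusted p = 2.26e-05; adjusted p = 0.595 with an estimated correlation). Of 16 autophagy and lysosome members 13 were higher in microglia and 2 called (adjusted p = 1.51e-06; adjusted p = 0.591 with an estimated correlation). The mitochondrial rise goes with the higher mitochondrial share of UMIs in rd1 microglia, so it was not told apart from cell quality. Glycolysis was lower in rods (18 of 20, adjusted p = 3.59e-06; adjusted p = 0.757 with an estimated correlation) and in cones (19 of 20, adjusted p = 2.92e-05; adjusted p = 0.435 with an estimated correlation). Interferon and MHC class I genes were higher outside Müller glia too, in rod bipolar cells (5 of 5, adjusted p = 0.00128; adjusted p = 0.999 with an estimated correlation), cone bipolar cells (10 of 14, adjusted p = 0.00953; adjusted p = 0.918 with an estimated correlation) and endothelial cells (15 of 22, adjusted p = 0.0130; adjusted p = 0.952 with an estimated correlation).

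As a hypothesis, alleles of the donor strain that flank Pde6b might add to the rod calls; the hypothesis and its bounds were written before its test was run, and a rule on the interval was added after the value was seen. Leaving out Pde6b, genes held mostly by other cells and genes not matched to a position, 7 of 256 genes within 20 Mb of Pde6b were called in rods (2.73%), against 367 of 10451 elsewhere (3.51%; odds ratio 0.772, 95% interval 0.305 to 1.63, Fisher exact p = 0.607). A share of at least 3 times the rest would have pointed to such alleles, and a share below 1.5 times argued against them. The observed ratio lies below the lower bound, but its interval reaches past it, so a modest excess stays open and a 3-fold one lies outside the interval. The 7 genes include Naaa (1.23) and Rasgef1b (−1.44), and 6 of the 7 were lower in rd1. Those nearest to Pde6b all fell: A930041C12Rik (−3.44), 1700028K03Rik (−1.56), Zfp605 (−1.07) and Glmn (−1.06). Zfp605 was also lower in each other class where it was measured (cones −0.56, rod bipolar −0.80, cone bipolar −0.64, amacrine −0.69, Müller glia −1.24), while Glmn went both ways. A stretch shorter than 20 Mb was not tested, so alleles close to Pde6b stay open.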
